A study of Mus musculus with 2 samples.

How the data were processed

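Total RNA was extracted with a Qiagen RNeasy kit from luminal epithelial cells of the mouse prostate that had been sorted by flow cytometry into GFP-positive and GFP-negative populations, per the labels' protocols. The GFP-positive cells are the label-retaining cells and the GFP-negative cells the non-retaining cells, both from mice of 18 weeks. Libraries were made with the Illumina TruSeq Stranded Total RNA kit, per the labels' protocols. The surface markers of the sort, the number of mice pooled and the sequencing batch are not given in the sources used here.

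The deposited table held 1 column for each of the 2 libraries and 18724 rows of Ensembl gene identifiers. Its values were a normalised signal, that is, gene read counts that the authors had divided by 1 size factor per library before they deposited them, as the values themselves show. All values of a column were whole multiples of a constant step, with a largest deviation from a whole number of reads of 5.2e-10 in the label-retaining and 4.4e-09 in the non-retaining column, so that 100% of values gave whole reads. The steps corresponded to size factors of 1.00 for the label-retaining and 1.10 for the non-retaining library. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, HTSeq 0.6.0, DESeq 1.16.0 and the mm10 genome build, without stating the role of each. The annotation, the handling of strand and of reads shared between genes, and the choice of rows are not given in the sources used here. Genes with near-identical copies, such as histone, haemoglobin, ribosomal protein, Svs3 and T-cell receptor genes, and genes that overlap others are therefore uncertain, because their reads could have been split or dropped. The product of the size factors was 1.10, whereas factors computed by the median-of-ratios method from these libraries alone would multiply to 1. The factors may thus have been computed together with other libraries. No row lay on the mitochondrial chromosome, and the mitochondrially encoded genes were not analysed here.

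Symbols, gene types and positions came from GENCODE release M21 on GRCm38, the assembly also called mm10. A symbol was found for 18634 identifiers, and 90 had none. The recovered reads summed to 50689229 in the label-retaining and 48334265 in the non-retaining library. The main scaling was the deposited one, as planned for a table that had already been divided by size factors. For each gene, the log2 ratio of the normalised counts (label-retaining over non-retaining) was computed with a pseudocount of 0.5 normalised counts in each library. An exact (Clopper-Pearson) 95% counting interval of the ratio was taken from the share of the gene's reads that came from the label-retaining library. The interval was 0.406 wide on each side on the log2 scale at 100 normalised counts and 0.125 at 1000 normalised counts. Genes with a mean normalised count of at least 10 were called measured, which kept 17183 and left out 1541.

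A measured gene was called higher or lower by size when its log2 ratio was at least 1 or at most -1 and its counting interval excluded equality. Each group had 1 library, so no test between the groups was run and no p-value or standard error was computed. Where a library had 0 reads of a gene, the fold was computed against a floor of 3 reads in that library. This bound is set by the floor and can lie farther from equality than the end of the counting interval. Each of 31 gene lists was summarised by its members called higher or lower, its median log2 ratio and a 95% order-statistic interval of that median. The median was also ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The lists cover luminal, basal, proximal luminal, stem, neuroendocrine, immune, vascular, stromal, seminal vesicle and red cell genes, the cell cycle, signalling pathways, stress, secretion, metabolism and ribosomal proteins.

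The calculation was tested on simulated counts drawn for the 17183 measured genes. All genes set 3-fold apart and all genes set 8-fold apart were called in the right direction. Counting noise alone gave calls for 67 unchanged genes, and 95.4% of unchanged genes had an interval that held equality. When unchanged genes were given an assumed biological coefficient of variation of 0.2, 542 were called, and with 0.4 it was 4160. Of those called, 0 and 1 were at least 16-fold apart.

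The genes named were chosen by a rule. It took the 15 higher and the 15 lower genes whose interval bound nearest to equality lay farthest from 0, among called genes with at least 50 normalised counts in the higher library, without predicted or unnamed genes. It also took up to 3 called members of each list by the same measure and the most abundant measured member, a set of genes named in advance (among them Krt5, Krt14, Trp63, Krt8, Krt18, Epcam, Cd24a, Dpp4, Pbsn, Mki67, Cdkn1a, Ly6a, Prom1 and Ptprc), and the 5 most abundant genes of each library. Some genes that the rule took are not reported here. Genes named outside the rule are marked where they appear as chosen after their values were seen. The lists, thresholds, naming rule and most alternatives were fixed before the data were examined. Synonyms that led to predicted genes were excluded from the lists after seeing the data.

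The alternatives were DESeq2 (1.42.0) median-of-ratios size factors, scaling on total counts, an abundance-dependent loess centring, no minimum count, a minimum of 50 normalised counts, a 4-fold threshold, an interval wholly beyond 2-fold, a pseudocount of 5, and genes without non-coding and predicted entries. A scaling that sets the mean log2 ratio of the luminal keratins Krt8 and Krt18 to 0, and edgeR (4.0.16) TMM factors, were added after seeing the data. DESeq2 and edgeR were used for scaling factors on the recovered reads, never as tests. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, R 4.3.3, and matplotlib 3.10.9 for plots.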

Results

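RNA was sequenced from luminal epithelial cells of the mouse prostate, sorted by whether they had kept a GFP label carried on a histone. Such a label is diluted at each division, so that cells which divide rarely keep it longer. The data were 1 library of label-retaining cells, with 50689229 reads in the genes of the table, and 1 library of non-retaining cells, with 48334265 reads. The comparison asks how label-retaining luminal cells, described in the study's title as progenitors that resist castration, differ in gene expression from the other luminal cells. All values compare these libraries, not the conditions. With 1 library per group there is no replicate check. The intervals of single genes cover counting error only. Those of list medians reflect the spread over member genes, which are not independent replicates.

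By the medians of the gene lists, the label-retaining library had less RNA of basal epithelial, smooth muscle and leukocyte genes than the non-retaining library, and more RNA of the lists of luminal identity, androgen-regulated and secretory, seminal vesicle secretion, and endoplasmic reticulum stress and secretory load genes. Of 17183 measured genes, 2483 (14.5%) were at least 2-fold higher in the label-retaining library by the size rule and 3330 (19.4%) at least 2-fold lower. Differences of 16-fold or more lay mostly on the lower side, with 399 genes lower and 44 higher when genes with 0 reads in 1 library are counted at their lower bound. The median log2 ratio of all measured genes was -0.0052. Scaled on the luminal keratins Krt8 and Krt18, a choice made after seeing the data that moves every ratio down by 0.76, the split became 960 higher and 6854 lower. Unchanged genes simulated with an assumed biological coefficient of variation of 0.4 gave 4160 calls at 2-fold and 1 at 16-fold. Many calls near 2-fold could thus arise from such variation alone. The simulation varied each gene independently, so it could not produce shifts shared by a whole list. It gave no count between these thresholds.

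**Figure D1:**
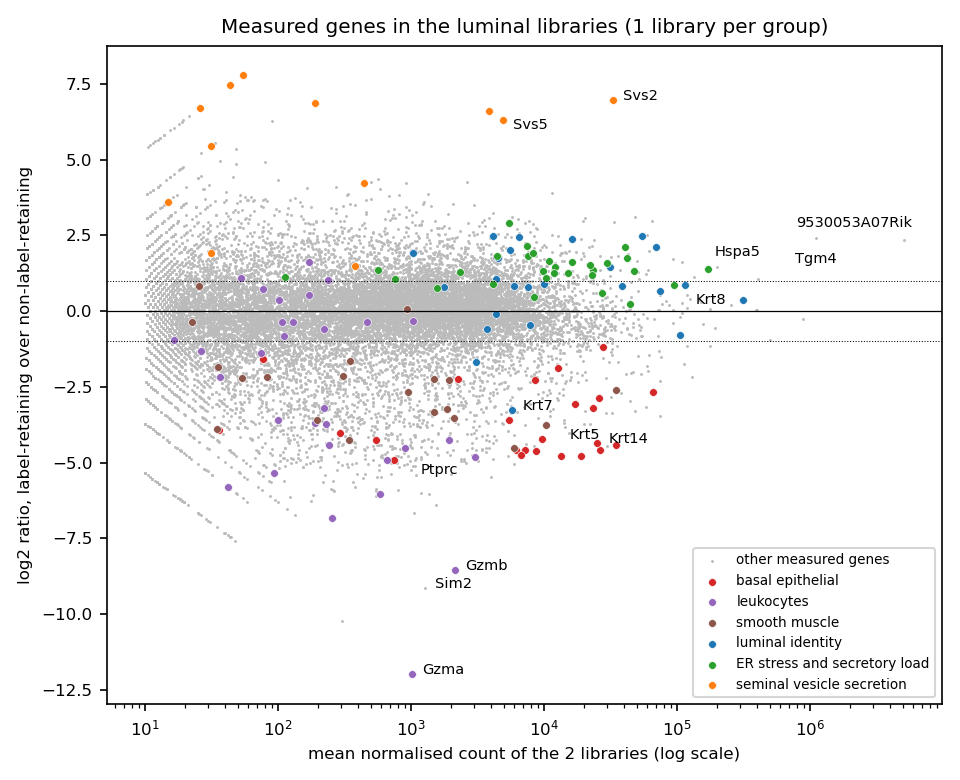
Log2 ratio of the label-retaining over the non-retaining library against mean normalised count (log axis) for each measured gene, with members of 6 gene lists in colour and dotted lines at 2-fold; genes with 0 reads in a library, such as Gzma, are placed by the pseudocount. All 24 measured basal genes lie below the lower dotted line and all 12 measured seminal vesicle genes above the upper one.

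Basal epithelial genes were lower without exception. All 24 measured members of the list were at least 2-fold lower in the label-retaining library, with a median log2 ratio of -4.13 (interval -4.59 to -2.88), and 0 of 10000 matched random lists had a median as low. Krt5, a keratin of basal cells (ENSMUSG00000061527.6, chromosome 15, 101707070 to 101712898, minus strand, mm10), had 962 reads against 28725 (log2 ratio -4.77, interval -4.86 to -4.67). Its partner Krt14 had 2124 reads against 55571 (-4.58, -4.64 to -4.51). Trp63, which encodes the basal transcription factor p63, had a log2 ratio of -4.74 (-4.87 to -4.61), and Col17a1, a hemidesmosome collagen, of -4.78 (-4.86 to -4.70). The listed basal genes held 0.144% of label-retaining reads and 1.42% of non-retaining reads.

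Luminal identity genes were more often higher than lower. Of 24 measured members, 10 were higher and 2 lower, with a median of 0.85 (interval 0.36 to 1.93), and 1 of 10000 random lists had a median as high. Krt19 was at 2.50 (2.47 to 2.52), Dpp4, which encodes the surface peptidase CD26, at 2.49 (2.41 to 2.58), Cd24a at 2.12 (2.11 to 2.14), and Prom1, which encodes CD133, at 2.02 (1.95 to 2.09). Krt8 (ENSMUSG00000049382.9, chromosome 15, 101996698 to 102004482, minus strand), a keratin of luminal cells, had 148223 reads against 89295 (0.86, 0.85 to 0.88). Krt18 (0.66, 0.65 to 0.67) and Epcam (0.82, 0.79 to 0.84) were also less than 2-fold apart. Krt7 went the other way, at -3.28 (-3.37 to -3.19). Under the keratin scaling 7 members were higher and 5 lower, the median was 0.09, and Krt18 turned to -0.10. Krt8 and Krt18, both members of this list, define that scaling, so these values follow from the shift.

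Androgen-regulated and secretory genes also had more higher than lower members, 18 against 7 of 38 measured, with a median of 0.95 (interval 0.21 to 1.49) that 0 of 10000 random lists equalled. Tgm4, the prostate transglutaminase, had 1871222 reads against 381907 (2.43, 2.42 to 2.43), and probasin, Pbsn, 295832 against 118979 (1.45, 1.44 to 1.46). Acpp, which encodes prostatic acid phosphatase, was lower at -4.34 (-4.53 to -4.17), as was the metalloreductase gene Steap4 at -4.17 (-4.34 to -4.02). The most abundant gene of both libraries, 9530053A07Rik, held 16.9% of label-retaining and 3.80% of non-retaining reads, with a log2 ratio of 2.36 (2.35 to 2.36). Under the keratin scaling 11 secretory members were higher and 10 lower, with a median of 0.18.

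The 12 measured genes of seminal vesicle secretion were all higher in the label-retaining library. Their median was 6.46 (interval 3.62 to 6.97), and 0 of 10000 random lists reached it. It was 5.17 with the 3 members that had 0 reads in the non-retaining library set to their bound, and 4.16 with a pseudocount of 5. Svs2 (ENSMUSG00000040132.6, chromosome 2, 164235929 to 164238466, minus strand) had 65699 reads against 574 (6.97, 6.85 to 7.09). Pate4 followed at 6.62 (6.32 to 6.96) and Svs5 at 6.30 (6.06 to 6.57). Svs6 had 110 reads against 0 and was 40.2-fold higher against the floor of 3 reads, with a counting interval that began at 5.01 on the log2 scale. Under the keratin scaling 11 of the 12 were still called higher.

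Genes of endoplasmic reticulum stress and secretory load were higher as a group, 24 of 30 measured members against 0 lower, with a median of 1.35 (interval 1.19 to 1.60) and 0 of 10000 random lists as high. Hspa5, the chaperone BiP (ENSMUSG00000026864.12, chromosome 2, 34771970 to 34777547, plus strand), had 250872 reads against 104094 (1.40, 1.39 to 1.41). Herpud1, of the pathway that degrades misfolded proteins, was at 2.13 (2.11 to 2.16), and Chac1, a target of the stress factor ATF4, at 2.90 (2.82 to 2.98). These genes moved with the secretory list, and under the keratin scaling 6 of the 30 stayed called higher.

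Stem and progenitor associated genes were lower more often than higher, 18 against 5 of 32 measured, with a median of -1.18 (interval -1.82 to -0.25) and 0 of 10000 random lists as low. Lrig1, a marker of epithelial stem cells, was at -4.12 (-4.27 to -3.97), Kit at -3.22 (-3.74 to -2.77), and Itga6, also a member of the basal list, at -1.17 (-1.20 to -1.15). Prom1 was among the 5 higher members. Genes of proximal or castration-resistant luminal cells split, with 8 higher and 12 lower of 25 measured and a median of -0.71 whose interval, -1.75 to 1.20, held 0, although 9 of 10000 random lists were as low. Within that list Krt19 was higher, whereas Ly6d (-3.75, -3.97 to -3.55) and Ly6a, which encodes the surface antigen Sca-1 (-1.62, -1.78 to -1.46), were lower. The basal list stood at -4.13 in the same libraries. The stem list had 2 higher and 23 lower members under the keratin scaling (median -1.94) and the proximal list 5 and 13 (median -1.47).

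The signalling lists had more lower than higher members in the label-retaining library, as had the basal list, but the median intervals of the Wnt and growth factor lists held 0. Notch pathway genes had 1 higher and 14 lower members of 26 (median -1.09, interval -2.33 to -0.61), with the ligand genes Jag2 at -4.59 (-4.71 to -4.47), a member of the basal list, and Dll1 at -3.66 (-3.83 to -3.50). Wnt genes had 6 higher and 13 lower of 29 (median -0.91, interval -1.67 to 0.04), with the receptor gene Fzd2 at -3.57 (-3.97 to -3.22). TGF-beta and BMP genes had 3 higher and 11 lower of 29 (median -0.62, interval -1.54 to -0.12), with Tgfb1 at -3.29 (-3.46 to -3.14). Epithelial growth factor genes had 4 higher and 15 lower of 30 (median -0.87, interval -2.30 to 0.26), with the receptor gene Fgfr2 at -3.45 (-3.52 to -3.38) and Igfbp5 at -3.74 (-3.79 to -3.68). Epithelial-mesenchymal transition genes had 4 higher and 14 lower of 23 (median -1.42, interval -3.01 to -0.49), with Twist2 at -5.39 (-6.19 to -4.76). The genes named above were all lower members. The highest member of each list, chosen after the values were seen, was Dll3 (1.71) for Notch and Sfrp1 (2.62) for Wnt. For the TGF-beta, growth factor and transition lists it was Bmpr1b (2.45), Btc (2.53) and Mmp9 (3.82). Of the 10000 random lists, 0 were as low as the Notch and transition medians, 1 as low as the Wnt median, 12 as low as the TGF-beta median and 2 as low as the growth factor median. With the keratin scaling the lower members numbered 20 (Notch), 19 (Wnt), 19 (TGF-beta), 17 (growth factor) and 17 (transition), and the higher ones 0, 2, 2, 2 and 2 in the same order.

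**Figure D2:**
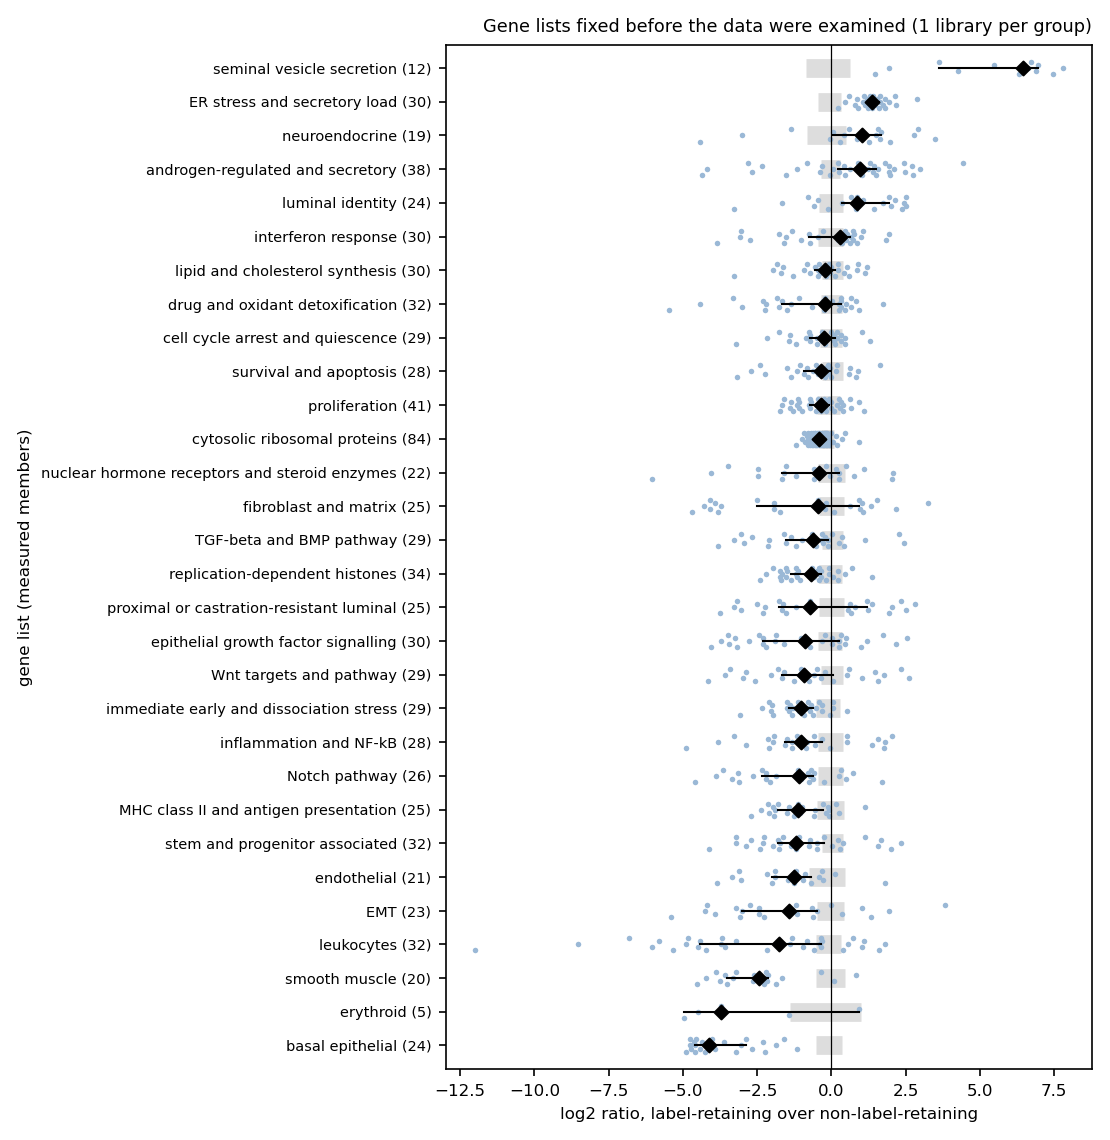
Log2 ratio of the label-retaining over the non-retaining library for the measured members (points) of each gene list, with the list's median (diamond), the 95% interval of the median (line) and the middle 95% of medians of matched random lists (grey bar). The medians run from -4.13 for basal epithelial genes to 6.46 for seminal vesicle secretion.

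Most cell cycle genes were not called by the size rule. Of 41 measured proliferation genes, 1 was higher, 10 lower and 30 neither, with a median of -0.35 (interval -0.73 to -0.08) at percentile 9.22 of the random lists. The members farthest apart were Mcm3 at -1.72 (-1.98 to -1.48) and Mcm5 at -1.66 (-1.91 to -1.41), both of the replication helicase, followed by Plk1 at -1.60. Mcm2, also of the helicase, was not called, at -0.24. The replication clamp gene Pcna was at -1.15 (-1.22 to -1.08). The proliferation marker Mki67 had 439 reads against 800 (-0.73, -0.90 to -0.56), under 2-fold. Replication-dependent histone genes had 1 higher and 16 lower of 34 (median -0.69, interval -1.37 to -0.35), and 16 random lists were as low. Arrest and quiescence genes had 2 higher and 6 lower of 29 (median -0.23, interval -0.72 to 0.10, percentile 11.6), with the growth-arrest gene Gas1 at -3.22 (-3.90 to -2.66) and Cdkn1a, the inhibitor p21, at -0.23 (-0.29 to -0.18). All 3 lists moved down under the keratin scaling, to a median of -1.10 with 0 higher and 23 lower for proliferation, -1.44 with 0 and 25 for histones, and -0.997 with 0 and 14 for arrest and quiescence. The basal list stood at -4.13 and the leukocyte list at -1.77 in these libraries. Whether the cell cycle differences came from luminal cells or from other cells in the sorts was not tested.

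Leukocyte genes were lower more often than higher, and the members farthest from equality were genes of T and natural killer cells. Of 32 measured, 4 were higher and 18 lower, with a median of -1.77 (interval -4.43 to -0.35) and 0 random lists as low. Gzma, a granule protease of killer cells, had 0 reads against 2234 and was 679-fold lower against the floor of 3 reads. The end of its counting interval nearest to equality was -9.11 on the log2 scale. Gzmb (ENSMUSG00000015437.4, chromosome 14, 56258838 to 56262260, minus strand) had 11 reads against 4705 (-8.54, -9.61 to -7.77), and Ptprc, which encodes the leukocyte antigen CD45, 208 against 6466 (-4.82, -5.03 to -4.63). The T-cell gene Cd3g was at -6.04 (-6.86 to -5.39), Tcrg-C1, a constant segment of the gamma receptor chain, at -6.12 (-7.01 to -5.44), and Icos at -5.95 (-6.78 to -5.31). Cd52, the most abundant listed leukocyte gene, was higher at 1.79 (1.72 to 1.86). Of 14 members that myeloid cells express, grouped after their values were seen, 3 were higher and 3 lower (median -0.35, interval -3.59 to 1.03). The lower ones were Itgax, Tyrobp and Fcer1g, which natural killer cells can express too, so that the tally of 0 lower among the other 11 depends on leaving them out. Genes of MHC class II and antigen presentation had 1 higher and 14 lower of 25 (median -1.12, interval -1.80 to -0.30, 1 random list as low), with H2-Ab1 at -2.10 (-2.22 to -1.98) and B2m at 1.14 (1.13 to 1.15). With the keratin scaling 1 leukocyte gene was higher and 25 lower, and 0 antigen presentation genes higher and 18 lower.

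Inflammation and NF-kB genes had 5 higher and 14 lower of 28 (median -1.03, interval -1.55 to -0.32, 0 random lists as low), with Ccl5, a chemokine gene that T and natural killer cells express, at -4.89 (-5.37 to -4.46) and the adhesion gene Icam1 at -3.29 (-3.36 to -3.23). Interferon response genes had 3 higher and 9 lower of 30. Their median was 0.30 and their mean -0.31, so the signs differed, the interval of the median (-0.77 to 0.64) held 0, the percentile was 94.2, and the median turned to -0.46 under the keratin scaling. Ifitm3 was at -3.06 (-3.14 to -2.99). Immediate early and dissociation stress genes had 0 higher and 15 lower of 29 (median -1.02, interval -1.44 to -0.61, 0 random lists as low), with Nr4a1 at -2.04 (-2.07 to -2.02) and Ier3 at -2.34 (-2.38 to -2.30). In the same libraries the basal list stood at -4.13 and the 8 T and natural killer cell members of the leukocyte list, grouped after their values were seen, at -5.92. The keratin scaling gave 3 higher and 20 lower inflammation genes, and 0 higher and 25 lower immediate early genes.

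Smooth muscle genes were lower in 17 of 20 members and higher in 0 (median -2.45, interval -3.52 to -2.15, 0 random lists as low), with the tropomyosin gene Tpm2 at -4.53 (-4.66 to -4.40). Endothelial genes had 1 higher and 13 lower of 21 (median -1.25, interval -2.004 to -0.68, 6 random lists as low), with the lymphatic gene Lyve1 at -3.85 (-4.19 to -3.54). Red cell genes had 0 higher and 4 lower of 5 (median -3.72, interval -4.95 to 0.92, 4 random lists as low), with the beta globin gene Hbb-bs at 201 reads against 6838. Fibroblast and matrix genes had 6 higher and 11 lower of 25 (median -0.44, interval -2.50 to 0.94, percentile 1.95), and 2 higher and 13 lower under the keratin scaling (median -1.20). Dcn, which encodes the proteoglycan decorin, was at -4.09 (-4.13 to -4.05) and the receptor gene Pdgfra at -4.68 (-5.07 to -4.34). Neuroendocrine genes had 10 higher and 3 lower of 19 (median 1.03, interval 0.05 to 1.67, 2 random lists as high), mostly from low counts, such as Scg2 with 36 reads against 3 (3.50, 2.06 to 6.06). Under the keratin scaling 4 neuroendocrine genes stayed higher and 3 lower, with a median of 0.28.

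Metabolic and housekeeping lists lay nearer to equality under the deposited scaling, with medians from -0.43 to -0.20, but not under the keratin scaling. Lipid and cholesterol synthesis genes had 2 higher and 6 lower of 30 (median -0.20, interval -0.55 to 0.11, percentile 8.41), with the elongase gene Elovl6 at -3.29 (-3.57 to -3.03). Detoxification genes had 1 higher and 13 lower of 32 (median -0.23, interval -1.67 to 0.32, percentile 11.6), with the efflux pump gene Abcb1a at -4.43 (-4.86 to -4.04) and the peroxidase gene Prdx6 at 1.74 (1.72 to 1.75). Survival and apoptosis genes had 1 higher and 8 lower of 28 (median -0.34, interval -0.92 to -0.04, percentile 1.94), with Bcl2 at -2.40 (-2.58 to -2.23). Nuclear hormone receptor and steroid enzyme genes had 3 higher and 9 lower of 22 (median -0.43, interval -1.67 to 0.27, percentile 2.76), with the vitamin D receptor gene Vdr at -4.06 (-4.24 to -3.89) and Cyp17a1 at 5 reads against 401 (-6.06, -7.82 to -4.96). Cytosolic ribosomal protein genes were less than 2-fold apart in 83 of 84 members, with 0 higher and 1 lower (median -0.41, interval -0.50 to -0.33, percentile 1.02), but 62 of them passed the lower threshold under the keratin scaling. That scaling gave 0 higher and 14 lower lipid genes (median -0.96), 0 and 16 detoxification genes (median -0.99), 0 and 14 survival genes (median -1.10), and 2 and 12 receptor and steroid enzyme genes (median -1.19).

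Some genes outside the lists stood far apart. Sim2, which encodes a transcription factor, had 4 reads against 2799 (-9.15, -11.19 to -7.96), Egln3, a hypoxia-induced prolyl hydroxylase, 40 against 2947 (-6.05, -6.56 to -5.62), and Col23a1, a transmembrane collagen, 176 against 8534 (-5.46, -5.69 to -5.25). On the higher side, Arl14, a small GTPase, had 5049 reads against 287 (4.27, 4.10 to 4.45), the sodium channel gene Scn4a 1090 against 57 (4.38, 4.01 to 4.80), and the mucin gene Muc19 1745 against 102 (4.22, 3.94 to 4.53). Among the most abundant RNAs, Malat1 was at 0.03 (0.02 to 0.03), Eef1a1 at 0.04 (0.03 to 0.04) and Actb at -0.96 (-0.96 to -0.95). Across 17111 genes with a transcript sequence, the Spearman correlation of the log2 ratio with transcript length was -0.06 and with GC content 0.011, genes not being independent replicates.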

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

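The keratin scaling and the TMM factors were chosen after seeing the data, and the other alternatives before. Under DESeq2 factors, TMM factors, loess centring, a pseudocount of 5, no minimum or a minimum of 50, both counts of genes stayed within 1.5 times the reported values and the medians of the 8 lists followed here within their intervals. The counts also stayed within 1.5 times for an interval wholly beyond 2-fold and without non-coding and predicted genes. Of the 2483 higher genes, 2483 stayed higher with DESeq2 factors and 1934 with total counts, and of the 3330 lower genes 3283 and 3330 stayed lower. The full tallies were fixed beforehand, because DESeq2 factors shifted all ratios up, by 0.013, and total counts shifted them down. Total counts shifted all ratios by -0.20, giving 1934 higher and 3976 lower, and the median of the endoplasmic reticulum list moved to 1.15. The keratin scaling shifted them by -0.76 and gave 960 higher and 6854 lower genes. Under it the list medians were 0.086 (luminal), 0.18 (secretory), -4.89 (basal), -1.94 (stem), -1.10 (proliferation) and 0.59 (endoplasmic reticulum). These moves follow from the shift itself. A 4-fold threshold left 742 higher and 1656 lower genes, fewer by construction. Of the other list medians, 1 moved beyond its interval with total counts and 10 with the keratin scaling, all downwards. Of the values of single genes, 377 of 1194 over 6 alternatives lay outside their counting interval, of which 165 were under the keratin scaling and 111 under total counts, all of these downwards. No gene called by size and named here, and no list whose interval excluded 0, changed sign under any alternative run. For called genes this was fixed beforehand, since their log2 ratios lie at least 1 from 0, beyond the largest shift of -0.76. Nor could a downward shift turn a list median that was below 0. No paired analysis was possible because each group had 1 library, and no library could be left out for the same reason. Depth limits genes of low count, where the counting interval at 100 normalised counts was 0.406 on each side.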

Other observations

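All genes and sets in this paragraph and the next were chosen after their values were seen, as were the tests weighed below, except the second basal list, which was written before its values were examined. The planned list of nuclear hormone receptors and steroid enzymes had 3 higher and 9 lower of 22 members, and the genes named next were picked from the higher side, so they show no direction for that group. Greb1, a target of the oestrogen receptor, had 3820 reads against 363 (log2 ratio 3.53, interval 3.37 to 3.69). The mineralocorticoid receptor gene Nr3c2 was at 2.08 (1.95 to 2.21) and the oestrogen receptor beta gene Esr2 at 2.03 (1.60 to 2.51), from 199 reads against 53, whereas the oestrogen receptor alpha gene Esr1, at 0.77 (0.70 to 0.84), was not called. Ren1, which encodes renin, had 115780 reads against 16163 (log2 ratio 2.97).

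Of 7 hypoxia-responsive genes, 4 were lower in the label-retaining library and 0 higher, with a median of -1.27 whose interval, -6.05 to 0.47, held 0; the set was picked after Egln3 was seen among the lowest genes. Egln3 was at -6.05, Angptl4 at -4.88 (-5.13 to -4.66), Ndrg1 at -2.33 (-2.39 to -2.27) and Slc2a1 at -1.27 (-1.31 to -1.24), and Vegfa (0.44, 0.40 to 0.49), Pdk1 (0.19, 0.06 to 0.32) and Bnip3 (0.47, 0.33 to 0.60) were less than 2-fold apart. Within the fibroblast list, the 8 collagen genes had 4 higher and 0 lower members with a median of 0.99 (interval -0.44 to 2.16), and the other 17 genes 2 higher and 11 lower with a median of -1.95 (interval -3.93 to -0.20). Under the keratin scaling 1 collagen gene stayed higher and 1 was lower, with a median of 0.23.

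Basal genes were lower in the label-retaining library in all 24 measured members of the first list, of which 5 belonged to another list as well. Basal cells in the non-retaining sort would bring their other abundant transcripts, and a second list of basal genes had 1 higher and 15 lower of 21 measured members, with a median of -3.41 (interval -4.17 to -0.37), which is consistent with that. The basal keratin gene Krt14 had 55571 reads in the non-retaining library, and a luminal gate, as the labels describe, would be meant to remove such cells. Luminal cells that themselves express basal genes cannot be told apart from a mixture, because each library pools its cells, and the mean log2 ratio of Krt8 and Krt18, 0.76, was short of the 2-fold that would have counted against them. A difference tied to label retention itself remained open and was not tested.

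Genes of T and natural killer cells were lower in the label-retaining library together with muscle, endothelial and red cell genes, while of 4 B cell genes 2 were lower and 2 were not called. A lower share of luminal cells alone in the non-retaining sort would raise the markers of every other cell type alike, if luminal cells made none of them, which was not tested. The basal and endothelial lists were fixed before the data were examined, but this pair was picked after their values were seen. Their medians differed by -2.88, the former minus the latter, with intervals of -4.59 to -2.88 and -2.004 to -0.68 that did not overlap. The endothelial interval also lay apart from that of smooth muscle genes (-3.52 to -2.15). It overlapped those of leukocyte (-4.43 to -0.35) and red cell genes (-4.95 to 0.92), as did the basal interval. The gaps to the endothelial list argue against an equal rise only if luminal cells made none of these genes. Because that condition was not tested, they do not decide. The 8 T and natural killer cell members of the leukocyte list were all lower, with a median of -5.92 and an interval ending at -3.21, whereas the interval of the 14 members that myeloid cells express, -3.59 to 1.03, overlapped theirs and excludes nothing. T and natural killer cells in the non-retaining sort are a candidate source. Of the measured T-cell receptor segments, 19 of 19 were lower, with a median of -5.59, or -4.72 with those at 0 reads set to their bound. Tcrg-C1 and Tcrg-C2 were already among the lowest genes taken by the naming rule, so this tally restates the pattern and does not test its source. Gzmb had 4705 reads and Gzma 2234 in that library, a luminal gate would be meant to remove such cells too, and no biological difference in immune cells between the groups was tested.

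Seminal vesicle genes were higher in the label-retaining library, and no member of that list belonged to another list. Seminal vesicle cells or RNA in the sample could bring them, and 12 of 12 measured members were higher, but prostate cells that express these genes would give the same count. Their levels were uneven, with 65699 reads of Svs2, 839 of Svs4 and 110 of Svs6 in that library. A larger share of anterior lobe cells could contribute, since Tgm4 and 9530053A07Rik, taken as genes of that lobe, were higher as well. They belong to 14 lobe-associated secretory genes, chosen after their values were seen, of which 11 were higher and 0 lower. The 14 were not split by lobe, so that tally does not measure the share of the anterior lobe. Of these 14, Spink1 (-0.03), Sbp (0.21) and Msmb (0.96) were not called. The seminal vesicle median lay 4.04 above the higher of Tgm4 and 9530053A07Rik, or 2.74 with members at 0 reads set to their bound and 1.74 with a pseudocount of 5. That gap does not decide, because other lobes may also make these genes, so these explanations and a difference tied to label retention cannot be told apart here.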
